A study of Canis lupus familiaris with 4 samples.

How the data were processed

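RNA sequencing was carried out on Madin-Darby canine kidney (MDCK) cells, an established epithelial line of dog kidney. Per the labels' protocols, the cells carried a tetracycline-inducible short hairpin RNA against STK11, the gene for the kinase LKB1, delivered with a lentiviral vector. The 4 libraries form 2 groups of 2, which the labels describe as independent experiments. The control libraries came from cells without tetracycline and the knockdown libraries from cells with it, so the drug and the knockdown changed together, and no library of cells given tetracycline without the hairpin was used here. Groups and replicate numbers were taken from the sample titles.

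The deposited values were made by the authors with kallisto 0.42.4 and the CanFam3.1 build of the dog genome, per the submitters' processing notes. Kallisto assigns reads to annotated transcripts without aligning them to the genome. The annotation release is not given in the sources used here. Per the file headers, each library has 1 table with the length, effective length, estimated counts and TPM (abundance corrected for transcript length) of each transcript, and the replicates were not pooled. The estimated counts deposited by the authors are not normalized and need not be whole, because a read that matches several transcripts is divided among them; 54.3% to 55.2% of the values above 0 in a library were not whole, to a tolerance of 1e-06. The TPM values deposited by the authors are corrected for effective length and sum to 1000000 in each library. No bootstrap estimates of the uncertainty of that division were used here, so transcripts of overlapping sequence can exchange reads in a way that replicate spread alone measures. In 125 sets of transcripts, 292 members in all, the length and the estimated counts above 0 were identical in every library.

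All 29881 rows carry an Ensembl transcript identifier and no gene name. The reference table at hand belongs to another dog assembly and holds Ensembl identifiers for none of its genes, and 0 of the 29881 identifiers matched it. The unit of every test was therefore the transcript, as foreseen in the design fixed before the data were examined. The level of STK11 and the 23 lists of genes fixed in that design, which need gene names, were not analysed here, nor were gene sums or genome positions.

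Estimated counts were rounded to whole numbers. Transcripts were kept by filterByExpr (minimum count 10, minimum total 15), which left 16882, and were normalized by the trimmed mean of M values (TMM). The groups were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided), with the group as the only term and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The fit had 2 residual degrees of freedom, with 3.52 added by the empirical Bayes prior. Standard errors were obtained from the fold change and the square root of F. CPM values are counts divided by the TMM-adjusted library size and scaled to 1000000 counts. The rule for naming items, also fixed beforehand, took the largest significant changes in each direction with an average log2 CPM of at least 1 and both knockdown libraries on the same side of both control libraries. It asked for 12 per direction with a gene symbol; without symbols, 2 per direction are named by identifier.

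The libraries held 21806811 and 22391648 estimated counts in the controls and 32092840 and 38558178 in the knockdown. A count of 0 allows up to 3 counts, which is 0.139 and 0.134 CPM in control replicates 1 and 2 and 0.0924 and 0.0779 CPM in knockdown replicates 1 and 2. These limits cover counting error only. Replicates were compared first. A chi-square statistic of their counts over transcripts with more than 20 counts was 17.3 per degree of freedom for the controls and 17.6 for the knockdown, which is above counting noise. This does not show whether the libraries are independent; each was counted as a sample of its own because the labels describe independent experiments.

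The tests were tried on simulated data made from the means, depths and dispersions of the 16882 transcripts, with 100 transcripts changed 2-fold and 100 changed 4-fold. The changed transcripts were drawn only from those above a minimum mean count, so the recovery rates do not cover rare transcripts. With a spread that varied between transcripts, the edgeR test recovered 33% of the 2-fold and 69% of the 4-fold changes with 6 false calls. DESeq2 recovered 65% and 93%, with 95 false calls. This spread was drawn around the fitted dispersions with the prior degrees of freedom of the real fit. Such draws lie above the fitted dispersions on average, so these rates need not hold for the real data. With equal spread at equal abundance the edgeR test recovered 83% and 95%, with 11 false calls.

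Of the alternatives fixed beforehand, 16 were run. They were the size factors of DESeq2, upper-quartile factors, no filter, a filter on CPM of at least 1 in 2 libraries, DESeq2 1.42.0, limma 3.58.1 on voom values and on log2(TPM + 1) and log2(TPM + 0.1), effective length as an offset, the replicate number as a block, a test against a fold of 1.5, robust empirical Bayes, and leaving out each library in turn. The test per transcript, listed as an alternative, became the main test, and the alternatives for gene lists and for STK11 were not run. After the data were seen, 2 more were added, counting identical transcripts once and thinning every library to the depth of the smallest.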

Results

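The transcriptome of MDCK cells, a polarized epithelial line from dog kidney, was compared between 2 control libraries without tetracycline and 2 libraries in which tetracycline induced a short hairpin RNA against STK11. STK11 encodes LKB1, a serine/threonine kinase that activates AMPK and related kinases, and the title of the series places it with a ciliopathy protein complex in the regulation of inflammation. The comparison asks which transcripts change when LKB1 is depleted in kidney epithelial cells. The libraries held 21806811 and 22391648 estimated counts in control replicates 1 and 2, and 32092840 and 38558178 in knockdown replicates 1 and 2. Estimated counts above 0 were found for 20246 and 20476 of the 29881 annotated transcripts in control replicates 1 and 2, and for 20597 and 20579 in knockdown replicates 1 and 2. The level of STK11 itself was not analysed here, because transcripts were not tied to gene names, so the labels were not checked against the targeted gene.

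Most of the MDCK transcriptome differed little between the groups. Of the 16882 transcripts tested, 85.9% had a fitted log2 fold change between -0.5 and 0.5, and the central 90% of fold changes ran from -0.71 to 0.56. The 10 transcripts with the highest mean TPM over the 4 libraries took 9.83% and 11.2% of the TPM in control replicates 1 and 2, and 10.2% and 10.7% in knockdown replicates 1 and 2. None of these 10 passed the threshold in the edgeR quasi-likelihood test; their adjusted p ranged from 0.184 to 0.959. The most abundant, a transcript of 132 bases, stood at 28241 ± 5839 TPM in the controls and 26576 ± 630.0 TPM in the knockdown (mean ± SD, n = 2).

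Libraries of the same group were nonetheless more alike than libraries of different groups. The first principal component of log2 CPM carried 50.7% of the variance and the second 30.2%. The positions of the libraries along these components are not given here, so the shares alone do not show a separation by group. Pearson's r of log2 CPM across transcripts, which are not independent replicates, was 0.986 between the controls and 0.991 between the knockdown libraries, and 0.978 to 0.983 between libraries of different groups. The biological coefficient of variation was 0.140 within the controls and 0.125 within the knockdown. In 49.2% of the tested transcripts both knockdown libraries lay on the same side of both control libraries, against 33.3% by chance for 2 against 2.

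In the knockdown, 18 transcripts rose and 56 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test). Among the transcripts that rose, the median log2 fold change was 1.14, and 12 rose by more than 2-fold. Among those that fell, the median was -1.07, and 31 fell by more than 2-fold. Changes of more than 4-fold were found in 3 of the transcripts that rose and 20 of those that fell. The smallest adjusted p was 0.00612, but all except a few of the calls lay between 0.0433 and 0.0498, just under the threshold. At an unadjusted p under 0.05 there were 2981 transcripts, where 844 would be expected if none changed. Of the calls, 18 higher and 54 lower transcripts had distinct values, and a refit of the data with identical transcripts counted once called 12 higher and 43 lower. The calls changed when a single library was left out, though such a fit also has fewer residual degrees of freedom to estimate the spread. Their number was 15 without knockdown replicate 1 and 2 without knockdown replicate 2, fits in which the lone library is assumed to vary like the control pair; it was 88 without control replicate 1 and 87 without control replicate 2. Of the 74 calls, 43 and 41 remained without control replicates 1 and 2, and 9 and 1 without knockdown replicates 1 and 2. With other tools the count was 811 in DESeq2 (346 higher, 465 lower), 158 in limma-voom (43 and 115) and 3 in limma on log2(TPM + 1) (1 and 2). With the replicate number as a block in edgeR it was 1503 (718 and 785), or 47.8% higher against 24.3% without the block; the labels do not say that equal numbers mark a shared experiment.

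**Figure D1:**
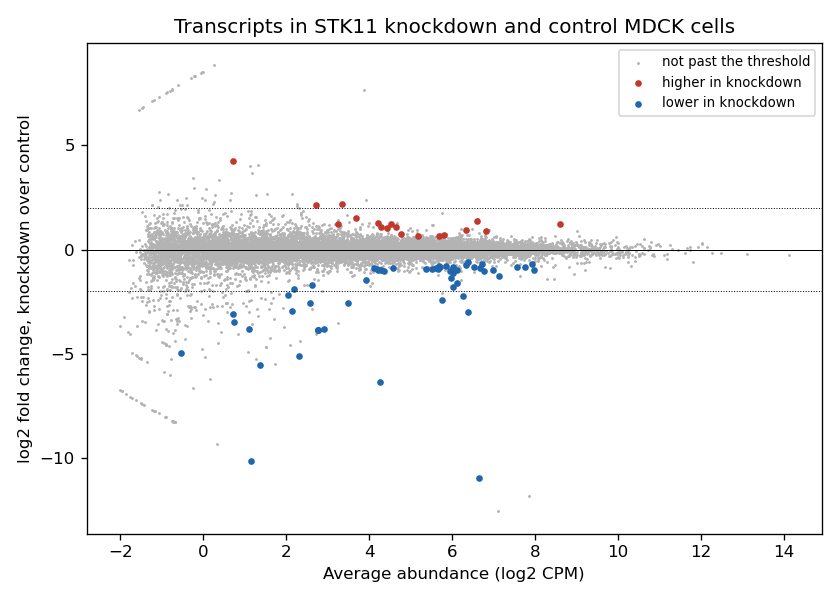
Log2 fold change of each of the 16882 tested transcripts (knockdown over control, vertical axis) against its average abundance in log2 CPM (horizontal axis). Each point is a transcript, the 18 that rose are red and the 56 that fell are blue, and dotted lines mark 4-fold changes, beyond which more points lie below than above.

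The changed transcripts were spread over the range of abundance. Of the 7789 transcripts with an average of 16 to 128 CPM, 12 rose and 33 fell. Of the 4771 with 2 to 16 CPM, 4 rose and 15 fell. Of the 1549 transcripts above 128 CPM, 1 rose and 5 fell, and of the 2773 under 2 CPM, 1 rose and 3 fell. The median absolute log2 fold change was 0.40 under 2 CPM and 0.12 above 128 CPM.

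The 2 named transcripts that rose were low in the controls and increased by about the same factor. ENSCAFT00000037581, of 2622 bases, stood at 3.61 ± 1.17 CPM in the controls and 16.2 ± 2.21 CPM in the knockdown (mean ± SD, n = 2). Its log2 fold change was 2.16 ± 0.25 (SE), a 4.48-fold increase, with an adjusted p of 0.0498 in the edgeR test. ENSCAFT00000028637, of 1387 bases, went from 2.35 ± 0.09 CPM to 10.3 ± 1.39 CPM (mean ± SD, n = 2), a log2 fold change of 2.12 ± 0.19 (SE) with an adjusted p of 0.0433 in the edgeR test. For the first, the adjusted p was 0.0503 with the size factors of DESeq2 and 0.0502 with upper-quartile factors, both just above 0.05. Without knockdown replicate 1 the log2 fold changes were 2.02 and 1.98 in the order named, with adjusted p of 0.151 and 0.132, and without knockdown replicate 2 they were 2.30 and 2.26, with adjusted p of 0.110 and 0.104.

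The 2 named transcripts that fell were almost or entirely undetected in the knockdown. Both belong to a small set abundant in a control library and near 0 in both knockdown libraries. The cause of that pattern stays open, as set out under Other observations. ENSCAFT00000029354, of 1453 bases, was at 107 CPM in control replicate 1 and 296 CPM in control replicate 2, and at 0.185 and 0.0260 CPM in knockdown replicates 1 and 2. Its fitted log2 fold change was -10.93 ± 0.91 (SE), with an adjusted p of 0.0433 in the edgeR test. The 2 controls differed by 2.77-fold, and in limma-voom the same transcript had a log2 fold change of -11.03 with an adjusted p of 0.172. ENSCAFT00000044782, of 2364 bases, stood at 4.84 ± 0.88 CPM in the controls (mean ± SD, n = 2) and had an estimated count of 0 in both knockdown libraries. With 3 counts in each knockdown library as the floor, it was at least 56-fold lower, with an adjusted p of 0.0433 in the edgeR test. Without knockdown replicate 1 the fitted log2 fold changes of these transcripts were -12.69 and -10.06 in the order named. Without knockdown replicate 2 they were -10.05 and -9.95. Neither transcript passed the threshold in these fits, and the folds of the second rest on knockdown counts of 0.

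**Figure D2:**
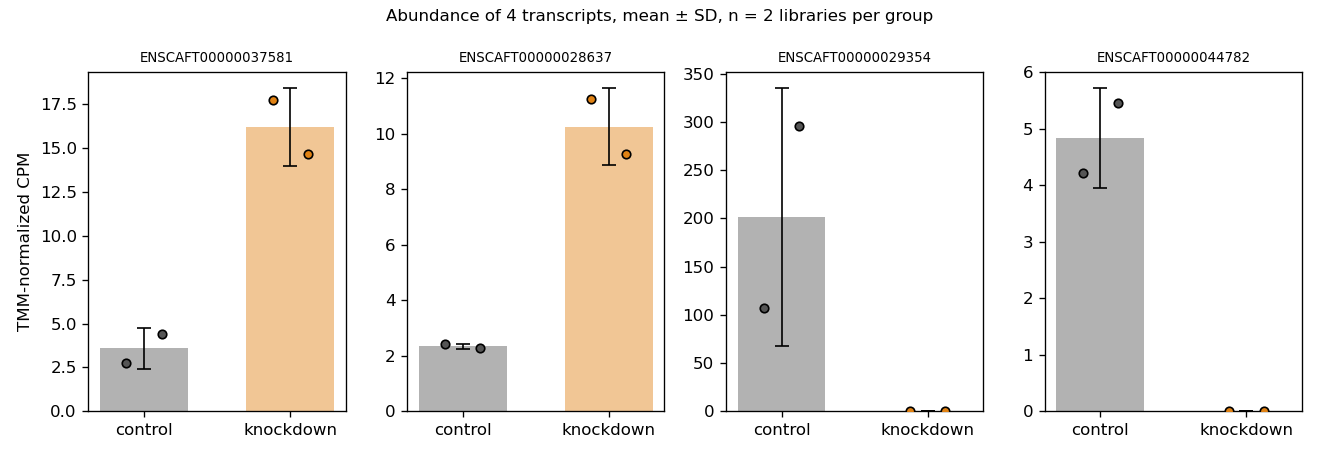
TMM-normalized CPM (vertical axis, starting at 0 in each panel) of the 4 named transcripts in control and knockdown cells. Points are libraries, bars the means and error bars the SD (n = 2); ENSCAFT00000029354 and ENSCAFT00000044782 were near or at 0 in both knockdown libraries, and the controls of ENSCAFT00000029354 lay at 107 and 296 CPM.

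Large differences were mostly decreases. Among all tested transcripts, whether or not they passed the threshold, 195 were lower and 54 higher in the knockdown by more than 4-fold, so that decreases made up 78.3%. Most of these transcripts were rare, with 146 of the lower and 42 of the higher under 2 CPM on average. In 184 of the lower and 46 of the higher transcripts, each knockdown library differed from each control library by more than 2-fold in the same direction. Between single libraries of different groups, decreases made up 59.5% to 67.8% of the changes beyond 4-fold. Between the 2 controls they made up 45.1% and between the 2 knockdown libraries 55.7%. Replicates of 1 group also differed in many transcripts. Beyond 4-fold, 134 were higher and 110 lower in control replicate 2 than in control replicate 1. For knockdown replicate 2 against knockdown replicate 1 these numbered 70 and 88. Pairs across groups had 118 to 151 higher and 201 to 249 lower in the knockdown library. Without control replicate 1 or control replicate 2 the higher transcripts numbered 169 and 164 and the lower 212 and 211, which brought decreases to 55.6% and 56.3%. Without knockdown replicate 1 or knockdown replicate 2, decreases made up 83.1% and 80.2%. With no filter on low counts 1525 transcripts were lower and 1422 higher, or 51.7% decreases. That set includes transcripts with very few counts, for which the greater depth of the knockdown libraries was not evened out.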

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

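All 18 alternatives gave the 4 named transcripts the direction reported. The naming rule took large changes with both knockdown libraries on one side of both controls. A reversal was therefore hardly possible, and the shared direction is no support. Of the 72 values, 48 kept an adjusted p under 0.05 and 24 did not. The ranges over the alternatives were 2.15e-09 to 0.161 for ENSCAFT00000037581, 1.3e-08 to 0.132 for ENSCAFT00000028637, 6.55e-15 to 0.172 for ENSCAFT00000029354 and 3.52e-08 to 0.0874 for ENSCAFT00000044782. The count of changed transcripts, 74 with 18 higher and 56 lower, moved by more than 1.5 times under most settings, and the cause was not tested except where named. It was 167 with no filter (47 higher, 120 lower), 126 with a CPM of at least 1 in 2 libraries (32 and 94), 811 with DESeq2 (346 and 465), 158 with limma-voom (43 and 115), 158 with robust empirical Bayes (48 and 110), 3 on log2(TPM + 1) (1 and 2), 13 on log2(TPM + 0.1) (3 and 10) and 1 in the test against a fold of 1.5 (0 and 1). Thinning all libraries to the smallest, chosen after seeing the data, gave 112 (29 higher, 83 lower). Of the 74 transcripts, 74 were also called by DESeq2, 73 by limma-voom and 2 on log2(TPM + 1). Leaving out each library in turn gave 2 to 88 changed transcripts, 0 to 33 higher and 1 to 61 lower. The share of higher calls was 24.3% in the main test, 42.7% in DESeq2 and 47.8% with the replicate block. Transcripts beyond 4-fold numbered 54 higher and 195 lower. They were 1422 and 1525 with no filter, 26 and 101 with a CPM of at least 1 in 2 libraries, 164 and 449 in DESeq2, 119 higher in limma-voom, and 3 and 43 on log2(TPM + 1), where the pseudocount compresses rare transcripts. Leaving out each library gave 56 to 169 higher.

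With the replicate number as a replicate block, 1503 transcripts passed (718 higher, 785 lower), including all 74 of the main test, with 1 residual degree of freedom and a prior of 6. The labels do not say that equal numbers mark a shared day or batch. The deviations of the libraries numbered 1 from their group means had a correlation of 0.17 across transcripts. With 2 pairs only, this does not settle whether equal numbers share something. The main test left the block out because the labels state no sharing, not because of this value. In simulated libraries without pairing and with varying spread, the block lowered recovery from 33% to 6% of 2-fold and from 69% to 62% of 4-fold changes. With equal spread, recovery was 83% and 95% without the block and 82% and 95% with it. In the real data the block raised the calls. The simulation changed only 100 transcripts 2-fold and 100 4-fold, and took its spread from the fit without the block. It therefore cannot decide whether equal numbers share something, and the design does not say. Depth limits the rare transcripts: 3 counts correspond to 0.0779 to 0.139 CPM per library. The gene-level and gene-list alternatives were not run for want of gene names.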

Other observations

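The tests of admixture and of the excess of decreases were chosen after the results were seen; those of transcript length were set after the pattern but before their outcomes were known.

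A small set of transcripts was abundant in a control library and near 0 in both knockdown libraries. With at least 5 CPM in a control and at most 0.2 CPM in each knockdown library there were 10 such transcripts, and 3 with the groups exchanged. Only 5 of the 10 and 1 of the 3 passed the filter and were tested. Of those tested, 3 and 0 passed the edgeR threshold. The 3 include ENSCAFT00000029354 and ENSCAFT00000044782, the 2 named transcripts that fell, so the explanations left open below apply to them too. A transcript of 403 bases stood at 17.3 and 536 CPM in control replicates 1 and 2, and at 0.032 and 0.0463 CPM in the knockdown. A transcript of 475 bases was at 0.158 and 223 CPM in the controls, and a transcript of 394 bases at 68.1 and 0.256 CPM. In the other direction, a transcript of 291 bases was at 49.0 and 7.60 CPM in knockdown replicates 1 and 2 and at 0.0967 and 0.182 CPM in the controls. If RNA from 1 other source had been mixed into both controls, these transcripts would share a ratio between the controls. With values under 3 counts raised to that floor, their log2 ratios (control replicate 2 over 1) instead ran from -8.05 to 10.47. Their SD was 5.04, much of it from transcripts near 0 in 1 control. The 5 that were tested were seen in both controls, and their ratios (replicate 2 over 1) ran from 0.681 to 31.0. These values argue against a single admixed source for the set as a whole. A different admixture in each control, a difference between the cultures, and a shift of reads between overlapping transcripts by the quantification all stay open, as does an effect of the knockdown or of tetracycline on the transcripts seen in both controls.

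The excess of large decreases, 195 against 54 beyond 4-fold, is a pattern that could come from the libraries or from the treatment. The knockdown libraries were deeper, but thinning all libraries to the smallest left decreases at 78.6%. Counting identical transcripts once left them at 78.0%. If 1 control library were the cause, falls would not outnumber rises where every library agrees. Among all tested transcripts in which each knockdown library differed by more than 4-fold from each control library in one direction, 99 fell and 26 rose, or 79.2% falls, which argues against it. The binomial 95% interval, 71.0% to 85.9%, treats transcripts as independent, which they are not, and so is too narrow; with sets of identical values counted once, 96 fell and 26 rose. Of the 195, 184 and 178 stayed more than 4-fold lower without control replicates 1 and 2. The share was 55.6% and 56.3% in those fits, because the higher transcripts rose from 54 to 169 and 164 while the lower numbered 212 and 211. Without knockdown replicates 1 and 2 it was 83.1% and 80.2%, so the share moved with the group left with a lone library. Transcripts removed by the filter on low counts went about evenly both ways, 1330 lower and 1367 higher beyond 4-fold when no filter was used. They have few counts, the knockdown libraries were deeper, and thinning was run only with the filter. Their split therefore cannot be read for or against the excess. With a CPM of at least 1 in 2 libraries falls made up 79.5%. The division of reads between related transcripts and a difference between the cultures stay open, as neither was tested. The treatment stays open too, and in it the design does not separate the knockdown from tetracycline.

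Short transcripts were slightly lower in the knockdown, and this may be variation between libraries. The median log2 fold change was -0.08 for the 389 tested transcripts of up to 300 bases and 0.03 for the 3889 over 4000 bases. With effective length as an offset, the median of the short class minus that of all transcripts was still -0.082, so differences in effective length do not account for it. The same class differed by a median of 0.086 between the 2 knockdown libraries and 0.066 between the 2 controls, as much as or close to the difference between the groups. The 4 differences between a knockdown and a control library were all negative, at -0.096, -0.026, -0.132 and -0.059. Neither variation between libraries nor an effect of the knockdown or of tetracycline is excluded.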
